A study of Caenorhabditis elegans with 8 samples.

How the data were processed

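The series holds 8 RNA-seq libraries of whole worms, 4 per group (NL, constant darkness; DL, 12 h light and 12 h dark), in a table of 47087 loci. The deposited values are FPKM, per the file headers, 1 column per library. Reads were aligned with HISAT2 and counted with HTSeq against WBcel235, per the submitters' processing notes; versions, annotation, strand setting and filters are not given in the sources used here. The kit named in the labels' protocols, NEBNext Ultra, does not mark strand. Of the loci, 46934 carry WormBase gene IDs and 153 are named as new loci; 44113 IDs matched a symbol or sequence name in the annotation of WBcel235 (Ensembl release 115), and 23953 loci were 0 in all libraries.

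The FPKM values of a gene are whole multiples of a step. With exon lengths from the annotation, 22881 of the 22985 genes used (99.55%) gave whole reads in all 8 libraries within a tolerance of 0.05 read. These reads described depth (18683546 to 20446464 reads per library) and noise only, apart from 2 alternatives. The total behind the deposited FPKM values was 0.936 to 1.156 times the recovered reads (1.156 in DL 1, 0.936 in DL 3), a scaling that the sources do not describe. No library pair of a group agreed within sampling noise: chi-square per gene was 8.54 for NL 1 and NL 2, 25.1 for DL 3 and DL 4, and 62.5 to 125 for the other pairs.

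Values were tested as log2(FPKM + 1), so that a log2 change understates the change of low genes. Genes with a mean of at least 1 FPKM over the 8 libraries were kept (14358). DL was compared with NL with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, an intensity trend, a two-sided test, Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The test, the lists, the named-gene rule and most alternatives were set before the data were examined. Limma's camera with a preset correlation of 0.01 tested 38 of 40 lists with at least 3 tested genes, adjusted over the lists. The mitochondrial genome list matched 0 symbols, and the male list had 2 tested genes of 16, so neither was tested. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.

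The labels give each replicate number a shared batch, so the numbers pair the libraries. The correlation of the deviations from the group means was -0.01, -0.19, -0.32 and 0.19 for the 4 pairs of a batch, and 0.59 for NL 3 and DL 2, which are of different batches. The fit without the batch, chosen in advance, is the main one, and the paired fit with the batch as a block called 25 genes against 101.

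Named genes were the 10 largest changes in each direction with limma adjusted p under 0.05, a mean of at least 5 FPKM in the higher group, a symbol other than a sequence name and the same sign in all 4 batches. To these came clock and light sensing genes that passed, with lin-42, kin-20, lite-1 and gur-3 in any case, up to 3 members of each other list that passed and at most 1 of a list that did not. The genes tps-1, tps-2, ugt-53, ugt-19, ugt-29, col-19, and the library values of vit-2 were chosen after the values were seen. The same steps were tested on simulated data of 14358 genes with 200 changed, for DL against NL. At the real spread, 47% of 2-fold and 85% of 4-fold genes were called, with 10 unchanged genes. Noise was drawn for each gene alone, so the simulation lacks differences between libraries that many genes share. Alternatives covered the pseudocount, the filter, the scaling, the batch block, each library and each batch left out, weights, covariates and the set test. Counting error alone sets the floor of 3 counts.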

Results

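Whole wild-type (N2) Caenorhabditis elegans were profiled by RNA sequencing of poly(A)-selected RNA in 8 libraries. Of these, 4 came from animals held in constant darkness (NL) and 4 from animals under cycles of 12 h of light (8000 lux) and 12 h of darkness (DL), at 20 °C. Each of 4 labelled batches held 1 library of each group. The labels place the animals at young adulthood after 40 h of culture and do not give the number of light cycles. They do not say whether the libraries of a group came from separate cultures, so the p-values below measure the spread between these libraries, which may be technical. The libraries held 18683546 to 20446464 reads assigned to genes, recovered from the step between low values, and 1 read in a gene of 1 kb was worth 0.0463 to 0.0546 FPKM.

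The series asks how a light and dark cycle changes the transcriptome relative to constant darkness. Transcripts of acdh-2, an acyl-CoA dehydrogenase family gene, and of clec-4, a gene for a C-type lectin domain protein, rose in DL, while those of ftn-1 (ferritin, which stores iron), sod-3 (a mitochondrial superoxide dismutase) and lipl-1 (a lipase) fell. Expression of acdh-2 was 6.63 ± 1.82 FPKM in NL and 61.8 ± 6.83 in DL (SD, n = 4 each), a log2 change of 3.07 ± 0.20 (SE; limma adjusted p = 0.0013). For clec-4 it was 8.76 ± 3.21 and 93.6 ± 45.8 FPKM, a log2 change of 3.19 ± 0.37 (limma adjusted p = 0.0114). Expression of ftn-1 was 65.6 ± 26.7 and 7.21 ± 3.2 FPKM, a log2 change of -2.97 ± 0.39 (limma adjusted p = 0.0165). For sod-3 it was 101 ± 32.4 and 19.8 ± 6.62 FPKM, a log2 change of -2.27 ± 0.29 (limma adjusted p = 0.0155).

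Among 14358 genes tested, 101 changed, 42 higher and 59 lower in DL, and 91 of them by at least 2-fold. The groups did not overlap for any of the 101, which were selected for a difference, so each also moved in the same direction in all 4 batches. Over all tested genes the groups did not overlap for 9.24% (2.86% by chance), and 24.7% moved in the same direction in all 4 batches (12.5% by chance). With the batch as a block, limma called 25 genes (13 higher, 12 lower), 23 of them among the 101. The block left 3 residual degrees of freedom against 6, so a call lost with it does not by itself show an effect of the batch. The count moved to 9, 9, 1561 and 221 without NL 1, NL 2, NL 3 or NL 4, and to 42, 134, 19 and 15 without DL 1, DL 2, DL 3 or DL 4. The lowest of these came on leaving out a library of the 2 most alike pairs, NL 1 with NL 2 and DL 3 with DL 4 (chi-square per gene 8.54 and 25.1). The 101 calls thus lean on pairs whose independence the labels do not give. Rescaling each library to the same sum turned the split to 41 higher and 33 lower, quantile normalization to 67 and 149, and centring on the median gene to 44 and 106. Without both NL 3 and DL 2, an alternative added after the data were seen, 1493 genes changed (1225 higher, 268 lower), all 101 among them.

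**Figure D1:**
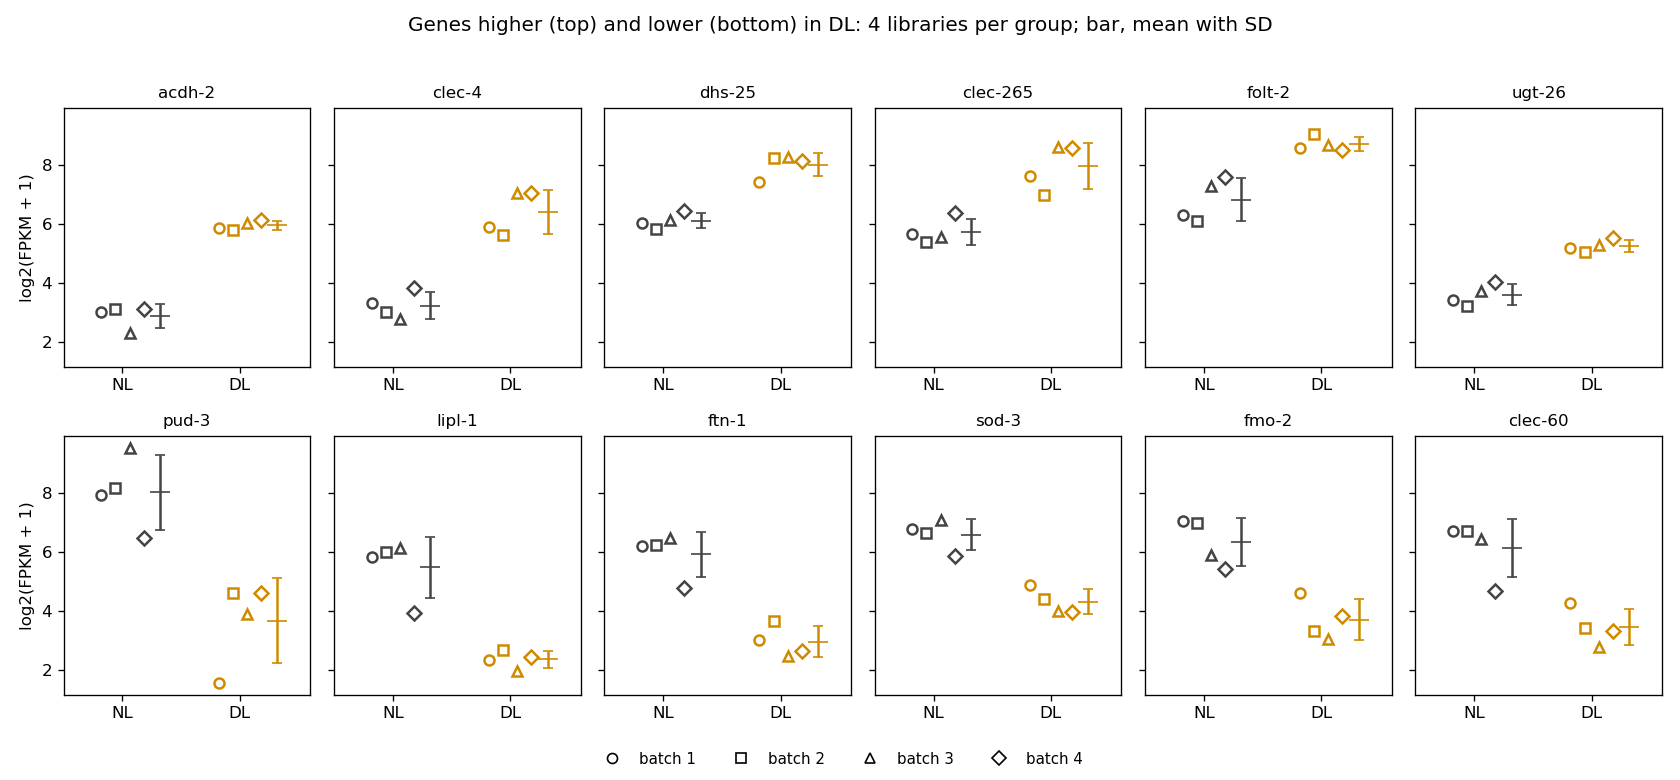
Expression of 12 named genes in each library as log2(FPKM + 1), with 6 genes that rose in DL in the upper row and 6 that fell in the lower row; symbols mark the batch and the bar gives the mean and SD of 4 libraries. For acdh-2 the mean FPKM was 6.63 in NL and 61.8 in DL, and for sod-3 it was 101 in NL and 19.8 in DL.

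The 10 largest rises by the rule fixed in advance also took in the short-chain dehydrogenase gene dhs-25, which went from 69.5 ± 12.9 to 267 ± 64 FPKM (log2 change 1.91 ± 0.22, limma adjusted p = 0.0114). The lectin domain gene clec-265 went from 55 ± 18.8 to 276 ± 134 FPKM (2.21 ± 0.38), clec-47 from 1.34 ± 0.866 to 20.4 ± 13.5 FPKM (3.01 ± 0.51) and folt-2, a folate transporter family gene, from 124 ± 60.4 to 427 ± 76.9 FPKM (1.90 ± 0.33). Log2 changes were 2.02 ± 0.25 for fbxc-58, 1.86 ± 0.33 for oac-32, 1.66 ± 0.20 for ugt-26 and 1.54 ± 0.22 for cyp-33C8. With the batch as a block, limma kept acdh-2 (adjusted p = 0.039), clec-4 (0.0461) and ugt-26 (0.0404). It no longer called dhs-25 (limma adjusted p = 0.0513), clec-265 (0.0528), fbxc-58 (0.0848), cyp-33C8 (0.0885), oac-32 (0.0942), folt-2 (0.136) or clec-47 (0.146). Of these lost calls, the SE was smaller with the block for dhs-25, clec-265 (0.26 against 0.38) and oac-32. It was larger for fbxc-58, cyp-33C8, folt-2 and clec-47.

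Among the largest falls, pud-3 went from 340 ± 281 to 15.7 ± 10.2 FPKM (log2 change -4.35 ± 0.78) and lipl-1 from 51.1 ± 25.3 to 4.22 ± 1.03 FPKM (-3.12 ± 0.45). The glutathione S-transferase gene gst-15 went from 36.6 ± 21.9 to 3.88 ± 0.654 FPKM (-2.73 ± 0.42), the flavin monooxygenase gene fmo-2 from 89.6 ± 46 to 13.3 ± 7.39 FPKM (-2.63 ± 0.44), and clec-60 from 80 ± 38 to 10.8 ± 5.34 FPKM (-2.69 ± 0.48). The comt-4 gene changed by -2.49 ± 0.36 and nspb-8 by -2.09 ± 0.19. With the batch as a block, nspb-8 (limma adjusted p = 0.0404), sod-3 (0.0461) and ftn-1 (0.0484) were still called. Calls were lost for fmo-2 (limma adjusted p = 0.0709), gst-15 (0.0773), lipl-1 (0.0821), clec-60 (0.0838), comt-4 (0.0915) and pud-3 (0.12). Among these the SE was larger with the block for comt-4 only, and for fmo-2 it was 0.34 against 0.44. The rule also named the piRNA locus 21ur-9814, which held 2, 4, 2 and 2 reads in NL and 0 in each DL library; both groups lie about the floor of 3 counts, so no fold is given.

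In the annotation of WBcel235, acdh-2 lies on chromosome II at 5544778 to 5547492, clec-4 on II at 12578331 to 12581113, ftn-1 on V at 7546468 to 7547579, sod-3 on X at 17092753 to 17094306, lipl-1 on V at 12919986 to 12921692 and pud-3 on V at 2324634 to 2325152. Values are per whole gene. The genes sod-3 and comt-4 overlap genes of the other strand, and acdh-2 and clec-60 overlap genes of the same strand. Reads of the shared parts cannot be told apart, across strands because the library kit does not mark strand, and the values of nspb-8, one of a family of similar genes, carry the same uncertainty.

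Homologs of animal clock genes and genes of light sensing, the groups closest to the question, held no gene that passed the test. Only 4 of 12 light sensing genes passed the expression filter, so most of that list was not tested. Of 11 measured clock homologs and these 4 light sensing genes, limma called 0 over all genes and 0 adjusted over the list alone. Unadjusted, 1 clock homolog and 2 light sensing genes had a limma p under 0.05. Among the clock homologs, lin-42, the homolog of period, stood at 45.4 ± 9.43 FPKM in NL and 63.1 ± 15.7 in DL (log2 change 0.45 ± 0.23, limma adjusted p = 0.302). The level of kin-20, a casein kinase 1 homolog, was 46.4 ± 14.3 and 34.5 ± 4.5 FPKM (-0.39 ± 0.20, limma adjusted p = 0.33). The photoreceptor gene lite-1 stood at 3.35 ± 0.813 and 3.29 ± 1.01 FPKM (-0.03 ± 0.23, limma adjusted p = 0.954). The related gene gur-3 lay below the expression filter, at 0.164 ± 0.161 and 0.13 ± 0.0638 FPKM. The camera adjusted p was 0.223 for the clock list and 0.851 for the light sensing list. The mean log2(FPKM + 1) of the 4 light sensing genes was 4.30 to 4.43 in NL and 4.44 to 4.61 in DL. These groups did not overlap (exact permutation of the libraries, two-sided, unadjusted p = 0.0286, the smallest possible). Of the 4 genes, 2 had positive and 2 negative log2 changes. In a simulation of DL against NL with 14358 genes, limma called 47% of the genes changed 2-fold and 85% of those changed 4-fold. Its changed genes were drawn from those above a set mean, with noise drawn for each gene alone. These shares therefore do not carry over to the lowest genes or to differences between libraries that many genes share.

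Genes of sperm and of oocytes and eggshell were higher in DL as lists by camera. All 50 sperm genes had positive log2 changes, with a median of 2.99; the camera adjusted p was 2.02e-21, and the adjusted p = 0.655 with an estimated correlation. Over all genes limma called 1 of them, and 47 adjusted over the list alone. The called member was ssp-32 (0.348 ± 0.28 to 3.67 ± 0.646 FPKM, log2 change 1.81 ± 0.23, limma adjusted p = 0.0155; 0.0824 with the block). The major sperm protein gene msp-10 stood at 2.65 ± 4.96 and 24.3 ± 19.3 FPKM (limma adjusted p = 0.0881). Of the 17 oocyte and eggshell genes 16 had positive log2 changes, with a median of 1.14 (camera adjusted p = 0.000867; adjusted p = 0.655 with an estimated correlation). Of these, limma called 0 over all genes and 0 adjusted over the list alone, and 7 had an unadjusted p under 0.05. With the sperm list mean as a covariate, added after the data were seen, the oocyte list turned lower (median -0.33, camera adjusted p = 0.00617). This covariate nearly follows the groups: of the NL libraries only NL 3 (4.23) lay in the DL range of 4.06 to 5.85. Fits with it, here and below, therefore lean on few libraries and do not single out stage.

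The libraries of a group were not alike in these genes. The mean log2(FPKM + 1) of the sperm list was 1.44, 1.62, 4.23 and 0.57 in NL 1 to NL 4 and 4.24, 5.85, 4.33 and 4.06 in DL 1 to DL 4. That of the oocyte list was 3.78 in NL 3 (DL 3.07 to 5.11, other NL 2.12 to 2.65). Similarly uneven was vit-2, which encodes a yolk protein of adult hermaphrodites: it stood at 0.354, 0.317, 51.3 and 0 FPKM in NL 1 to NL 4 and at 3.86, 120, 1.90 and 2.58 in DL 1 to DL 4. A collagen gene of the adult cuticle, col-19, stood at 1.19, 1.14, 41.8 and 0.0561 FPKM in NL and 2.19, 103, 4.1 and 3.3 in DL. Although the labels give young adulthood for all 8 libraries, these 2 transcripts of adults stood at 41.8 FPKM or more in NL 3 and DL 2 and at 4.1 or less in the other 6. The 6 were not alike: both transcripts stood at 1.90 to 4.1 FPKM in DL 1, DL 3 and DL 4 and at 0 to 1.19 in NL 1, NL 2 and NL 4. The first principal component (53.4% of the variance) put NL 3 at 19.1, beside DL 1, DL 3 and DL 4 at 26.4, 26.8 and 23, with the other NL libraries at -56.6, -53.4 and -63 and DL 2 at 77.6. The vitellogenin list, with a median log2 change of 0.21 in its 5 genes, had a camera adjusted p of 0.688.

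**Figure D2:**
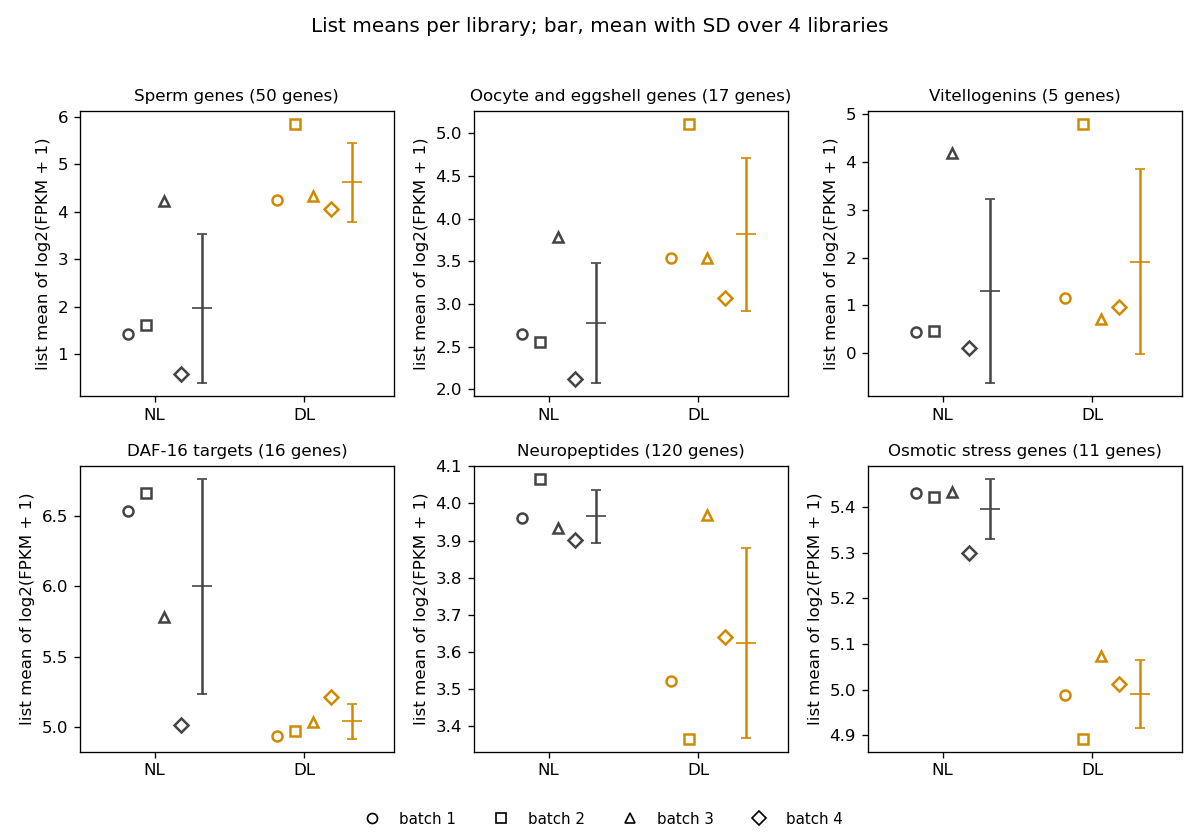
Mean of log2(FPKM + 1) over the genes of 6 lists in each library; symbols mark the batch and the bar gives the mean and SD of 4 libraries. In the sperm list NL 3 stood at 4.23, among the DL libraries at 4.06 to 5.85, and in the vitellogenins NL 3 and DL 2 stood apart from the other libraries of their group.

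Also higher in DL were core histones (34 genes, median 0.32, camera adjusted p = 0.0131), germline genes (20 genes, 0.39, 0.0105), cell cycle and replication genes (22 genes, 0.18, 0.0243) and genes of the unfolded protein response of the endoplasmic reticulum (16 genes, 0.27, 0.0174). With an estimated correlation the adjusted p = 0.682 for the histone, germline and cell cycle lists and the adjusted p = 0.655 for the unfolded protein response. Over all genes, limma called 0 members of these 4 lists (4, 3, 2 and 4 had an unadjusted p under 0.05); adjusted over the list alone, 2 genes of the unfolded protein response passed. The chaperone gene hsp-4 stood at 162.6 ± 10.7 FPKM in NL and 304 ± 57.5 in DL (log2 change 0.88 ± 0.17, limma adjusted p = 0.0541). Relative to the other libraries of their groups, the germline list mean stood 0.45 higher in NL 3 and 0.61 higher in DL 2. The means of all 4 NL libraries in the histone list (3.18 to 3.39; DL 3.10 to 4.02), of NL 2 and NL 3 in the germline list (4.16 and 4.34; DL 4.14 to 4.85), of NL 3 in the cell cycle list (4.76; DL 4.71 to 5.18) and of NL 4 in the unfolded protein response (7.14; DL 7.11 to 7.45) lay within the DL range. With the sperm list mean as a covariate the germline list turned lower (median -0.22, camera adjusted p = 0.0341) and the cell cycle list did not pass (median -0.0013, camera adjusted p = 0.868). In that fit the histones (median 0.50, camera adjusted p = 0.000135) and the unfolded protein response (median 0.32, camera adjusted p = 0.000159) stayed higher. Without NL 3 and DL 2 the camera adjusted p of these 4 lists was 0.132, 0.0512, 0.309 and 0.154.

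Targets of the transcription factor DAF-16 were lower in DL as a list by camera. Of 16 measured targets 14 had negative log2 changes, with a median of -0.78 (camera adjusted p = 3.88e-05; adjusted p = 0.655 with an estimated correlation). Of them sod-3 and ftn-1 fell, 3 targets passed adjusted over the list alone, and daf-16 itself stood at 51.7 ± 3.17 and 36.4 ± 4.36 FPKM (limma adjusted p = 0.0991). NL 4, at a list mean of 5.01, lay among the DL libraries (4.94 to 5.22), while NL 1, NL 2 and NL 3 stood at 6.53, 6.67 and 5.78. Of 11 osmotic stress genes 10 had negative log2 changes, with a median of -0.34 (camera adjusted p = 0.0105; adjusted p = 0.655 with an estimated correlation; fry adjusted p = 0.0153). In that list limma called 0 genes over all genes and 0 adjusted over the list alone, and 5 had an unadjusted p under 0.05. The trehalose synthase genes tps-1 and tps-2 had log2 changes of -0.81 and -0.67. Both lists stayed lower with the sperm list mean as a covariate. The DAF-16 targets then had a median of -0.72 (camera adjusted p = 0.000315) and osmotic stress -0.30 (camera adjusted p = 0.0392).

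Genes of neurons and muscle were lower in DL as lists. Of 120 neuropeptide genes 108 had negative log2 changes, with a median of -0.35 (camera adjusted p = 1.55e-10; adjusted p = 0.655 with an estimated correlation). All 16 muscle genes were negative, with a median of -0.41 (camera adjusted p = 0.000138), and so were 15 of 16 neuronal genes (-0.29, 0.0028) and 14 of 17 genes of neurotransmitter synthesis and transport (-0.27, 0.0177). With an estimated correlation the adjusted p = 0.655 for each of these 3. Among the members of the 4 lists limma called 0 over all genes (33, 5, 3 and 4 had an unadjusted p under 0.05), and adjusted over the list alone 1 passed, a muscle gene. In NL 3, whose sperm list mean lay among the DL libraries, the muscle list mean was 7.57 (DL 7.50 to 7.96, other NL 8.05 to 8.51), the neuronal 4.34 (DL 4.05 to 4.50, other NL 4.54 to 4.65) and the neurotransmitter 2.90 (DL 2.72 to 2.96, other NL 2.98 to 3.20); the neuropeptide means of NL 1, NL 3 and NL 4 (3.90 to 3.96) lay within the DL range (3.37 to 3.97). With the sperm list mean as a covariate, the medians of the muscle, neuronal and neurotransmitter lists were -0.02, 0.019 and 0.013 and none passed (camera adjusted p = 0.868, 0.988 and 0.887), while the neuropeptides stayed lower (median -0.20, camera adjusted p = 0.00721). A troponin I gene of muscle, tni-1, stood at 151 ± 25.1 and 94.1 ± 5.1 FPKM (limma adjusted p = 0.07), ins-35 at 53.9 ± 22.2 and 20.7 ± 6.2, and egl-3, which encodes a neuropeptide-processing convertase, at 85.7 ± 19.4 and 61.7 ± 10.1 (limma adjusted p = 0.213).

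Heat shock genes (16 genes, median -0.65, camera adjusted p = 0.0105) and genes of autophagy and the lysosome (22 genes, -0.21, 0.0201) were lower as lists, with 0 members called by limma over all genes, 0 adjusted over the list alone, and 2 and 1 with an unadjusted p under 0.05. With an estimated correlation the adjusted p = 0.655 for both. NL 3 and NL 4 lay within the DL range in both lists: heat shock means were 5.03 and 5.22 (DL 4.71 to 5.46; NL 1 and NL 2 5.86 and 5.69) and autophagy means 5.51 and 5.56 (DL 5.4 to 5.64; NL 1 and NL 2 5.98 and 6.04). With the sperm list mean as a covariate neither passed (camera adjusted p = 0.887 for each). Cuticle collagens were called lower (150 genes, camera adjusted p = 0.0301; adjusted p = 0.838 with an estimated correlation; 0.0529 with the block), although the median of -0.28 and the mean of 0.05 differ in sign. Of them col-163 (5.76 ± 3.1 to 0.875 ± 0.198 FPKM, limma adjusted p = 0.0364) and col-123 (30.3 ± 12.31 to 6.72 ± 2.48 FPKM, limma adjusted p = 0.0397) fell, calls that the block did not keep (limma adjusted p = 0.129 and 0.0922), and adjusted over the list alone 1 was higher and 9 lower. The collagen list mean stood 0.75 higher in NL 3 and 0.89 higher in DL 2 than in the other libraries of the group, and all 4 NL means (5.05 to 6.32) lay within the DL range (5.03 to 6.48). Collagens stayed lower with the sperm list mean as a covariate (median -0.40, camera adjusted p = 1.05e-11).

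**Figure D3:**
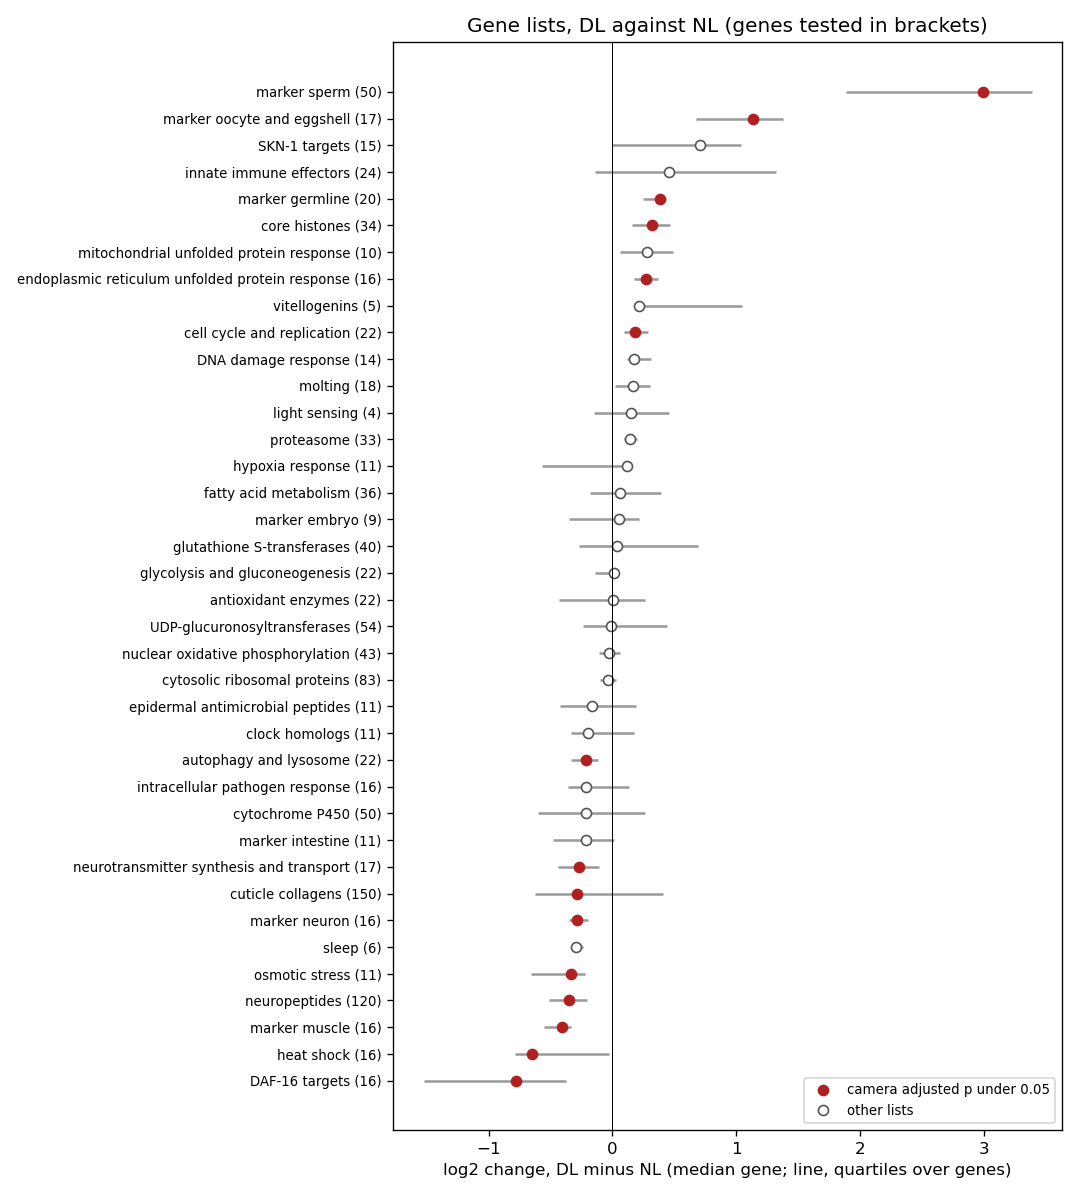
Median log2 change, DL minus NL, of the tested genes of each of 38 lists, with the quartiles over genes as a line; filled points mark lists with a camera adjusted p under 0.05. The sperm list stood at 2.99 and the DAF-16 targets at -0.78.

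In all 15 of 38 lists passed camera, 6 higher and 9 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.655. That correlation was 0.872 for the sperm list, 0.505 for the DAF-16 targets and -0.0452 for osmotic stress, against the preset 0.01. For osmotic stress the estimate lay below the preset, so the correlation alone does not account for the lost call. The simulation ran camera with the preset only, so the power with an estimated correlation was not tested. By exact permutation of the libraries (two-sided, unadjusted), the list mean gave p = 0.0286 for osmotic stress, the smallest p possible. The DNA damage response and light sensing lists, which did not pass camera, gave the same permutation p. For the other lists that passed camera the permutation p ran from 0.0571 (sperm among them) to 0.829 (collagens), with 0.0857 for the DAF-16 targets. Without NL 3 and DL 2, 12 lists passed camera. With the batch as a block 17 passed: SKN-1 targets (camera adjusted p = 0.00992 against 0.054), innate immune effectors (0.0399 against 0.054) and cytochrome P450 genes (0.0466 against 0.054) were added and the collagens lost. The first 2 were higher as lists, and the P450 genes lower (median -0.22), although limma called 2 of their members, both higher, cyp-33C8 among them. In the fit with the block and an estimated correlation the 3 lists had an adjusted p = 0.704, 0.73 and 0.704. Genes of the immune list moved both ways: clec-4 rose, fmo-2 and clec-60 fell, and adjusted over the list alone 11 were higher and 3 lower of 24. Of 54 UDP-glucuronosyltransferase genes (camera adjusted p = 0.688), ugt-26, ugt-53, ugt-19 and ugt-29 rose, the last 3 no longer called with the block (limma adjusted p = 0.104, 0.0861 and 0.108), and adjusted over the list alone 8 were higher and 2 lower.

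The other lists that did not pass had camera adjusted p-values of 0.0729 (proteasome and DNA damage response), 0.0849 (hypoxia response), 0.119 (mitochondrial unfolded protein response and intestine), 0.2 (sleep and intracellular pathogen response), 0.396 (antioxidant enzymes), 0.44 (cytosolic ribosomal proteins), 0.479 (nuclear oxidative phosphorylation) and 0.571 (epidermal antimicrobial peptides). For glycolysis, molting and fatty acid metabolism it was 0.688, for embryo markers 0.746 and for glutathione S-transferases 0.816. The median and the direction of camera differ in sign for the hypoxia response (median 0.12, direction lower), the embryo markers (0.05, lower), antioxidant enzymes and glycolysis (0.01, lower) and the UDP-glucuronosyltransferases (-0.01, higher).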

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

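The tests of the library that stands apart and of developmental stage, and the values without NL 3, were chosen after the result was seen. The stage test was parted into genes higher and lower in DL only when its value over all genes and both parts were known. The counts over splits and the test of msp genes were planned before. For library scaling the limit was written before its result, but the scaling to recovered reads was itself chosen after the data were seen. A library was far from the other 3 of its group for 21 of 142 combinations of group with a gene named in the text, the mean of a list or a library property; chance gives about 1 in 20.

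Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, reached 101 changed genes, and the highest other gave 3. This is the smallest share that 35 splits can give, so the count passed the planned limit of 5%, which does not exclude chance. The 8 splits that part all 4 batches, where the highest other also gave 3, are too few for a share under 5%. Limma called 25 genes with the batch as a block and 0 without batch 1 (2199 at an unadjusted p under 0.05). Scaling to recovered reads called 82.2% of the 101 again, which argues against the authors' library scaling as the cause of most of these calls. Quantile normalization called 96% again, centring on the median gene 94.1% and rescaling to the same sum 58.4%. The calls thus depend in part on the scaling. Between the other NL libraries (0) and DL (1), the median position of NL 3 was 0.797 over the 1561 genes called without it, so a developmental stage shared by NL 3 and the DL libraries may account for many of them; the median was 0.837 over the 1175 higher in DL and 0.387 over the 386 lower, which leaves stage undecided for the lower genes and does not decide whether NL 3 is a mislabelled DL library (quartiles -0.07 to 0.745; mean correlation of NL 3 0.943 with DL and 0.919 with the other NL libraries). By the same measure NL 4, with no vit-2 reads, lay at 0.516 over its 221 genes (0.423 over the 61 higher, 0.586 over the 160 lower). DL 2 lay at 0.426 from the other DL libraries towards NL over its 134 (0.504 over the 85 higher, 0.189 over the 49 lower). A position of 0.4 to 0.6 is thus not particular to a later stage. Over the genes higher in DL, NL 3 lay further across: 88% of its genes were nearer the other group, against 37.7% for NL 4 and 52.9% for DL 2. Over the lower genes its 0.387 lay between those of DL 2 and NL 4. In all 101 genes, called with NL 3 in its own group, NL 3 lay outside the DL range on the NL side, which follows in part from how they were called. Light, stage and a wrong label of NL 3 stay open, light and stage because both separate DL from NL 1, NL 2 and NL 4. With the sperm or the oocyte list mean as a covariate, limma called 37 and 60 of the 101 again. In both lists NL 3 alone of the NL libraries lay within the DL range, so these fits do not part light from stage. The biological effect of light was not otherwise tested apart from stage.

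For the lists, 13 of the 35 splits passed at least the real 15, with 19 in the highest other, so a chance split of the libraries cannot be excluded for the number of lists. The 8 splits that part all 4 batches, where the highest other passed 18, are too few for a share under 5%.

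Camera called the sperm and oocyte lists higher in DL. The sperm list mean of NL 3 was 4.23, within the DL range of 4.06 to 5.85 and above the other NL libraries (0.57 to 1.62), so stage differences between libraries whatever their group may account for the lists. Members of the sperm list that are not msp genes had a median log2 change of 1.81, which argues against reads shared among near-identical msp genes as the whole cause. A shift of stage with the light cycle stays open and was not tested.

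Values are on the log2(FPKM + 1) scale, with the gap to the nearest library as a share of the range of the group. NL 3 was far from the other NL libraries for acdh-2 (0.884, low), nos-2 (0.867, high), vit-2 (0.923, high), the vitellogenins (0.914, high) and the scaling of the library (0.907, high). NL 4 was far from them for ftn-1 (0.84, low), lipl-1 (0.861, low), clec-60 (0.863, low), kin-20 (0.847, high), the osmotic stress list (0.917, low) and the endoplasmic reticulum unfolded protein response (0.888, high). NL 2 was far for 21ur-9814 (0.928, high) and NL 1 for ugt-29 (0.889, high). In DL, DL 2 was far for kin-20 (0.895, low), col-19 (0.865, high), vit-2 (0.862, high), the sperm list (0.85, high) and the vitellogenins (0.892, high). DL 1 was far for dhs-25 (0.845, low) and daf-16 (0.891, high), and DL 4 for nspb-8 (0.862, low).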

How the results depend on the processing

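The covariates, the fit without NL 3 and DL 2, the scaling to recovered reads, the protein-coding filter and the fit on recovered reads were chosen after the data were seen. The analysis of the report called 101 genes (42 higher, 59 lower) and 15 lists. Without a filter on low values limma called 33 (16 higher, 17 lower), with quantile normalization 216 (67, 149), with the batch as a replicate block 25 (13, 12), with array weights 5189 (3002, 2187) and without NL 3 and DL 2 1493 (1225, 268). Rescaling libraries to the same sum gave 33 lower genes and centring on the median gene 106 lower. With the sperm list mean as a covariate limma called 92 (24 higher, 68 lower), 37 of them among the 101. With the oocyte list mean it called 148 (77, 71), 60 of them among the 101. Both covariates nearly follow the groups, so these fits do not single out stage. Leaving out libraries or batches gave 0 to 1561 genes, 0 to 1175 higher and 0 to 386 lower; the 0 came without batch 1, where 2199 genes had an unadjusted p under 0.05. Of the lists, 0 passed with an estimated correlation and 1 by fry. The cause was not tested.

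The other alternatives stayed within 1.5 times the main count. Of 661 values of the 23 called named genes over the alternatives, 0 reversed and 439 were called again, from 28 of 29 for acdh-2 (limma adjusted p 8.2e-06 to 0.0839) to 9 of 29 for clec-60. The lists that passed kept call and direction in 16 (cell cycle), 17 (collagens) and 18 (autophagy) of 28 alternatives at the low end. The highest was 27 of 28, for osmotic stress.

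With the sperm list mean as a covariate, log2 changes turned sign for cyb-1 (-0.0399), cyb-2.1 (-0.30), gld-1 (-0.36), his-70 (-0.16), kin-20 (0.11), lite-1 (0.30), nos-2 (-0.0291), pgl-1 (-0.0343), puf-3 (-0.25), puf-5 (-0.33), rpn-6.2 (-0.32), sdz-27 (-0.49) and vit-2 (-3.72). The direction given by camera turned, as did the median, for the germline (-0.22), oocyte (-0.33), autophagy (0.0083) and neurotransmitter (0.013) lists. The median also crossed 0, with camera's direction kept and its call lost, for the neuronal (0.019) and cell cycle (-0.0013) lists, and for the sperm list itself (-0.012), which this covariate takes out by construction; the muscle median fell to -0.02. With the oocyte mean as a covariate lite-1 (0.21) and vit-2 (-1.73) turned; the germline median fell to 0.0032 without turning, while camera's direction turned, and the oocyte median, taken out by construction, was -0.00385. Without NL 3 and DL 2 lite-1 was at 0.023. Over the fits that leave out a library or a batch, the collagen median ran from -0.40 to 0.11, lite-1 from -0.17 to 0.22 and vit-2 from -0.16 to 3.40. The planned models for raw counts were not run, because the values are FPKM.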

Other observations

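The families and the mitochondrial genes here were chosen after the result was seen. Of 125 gene families of at least 10 tested genes, 31 passed camera and 0 with an estimated correlation. The nspb and fipr families were among those lower in DL: all 11 nspb genes had negative log2 changes (median -1.23; camera adjusted p = 1.57e-11; adjusted p = 0.648 with an estimated correlation), of which 4 were called by limma and 1 of these, nspb-8, also with the batch as a block, and 15 of 17 fipr genes did (median -1.25; camera adjusted p = 1.61e-09; adjusted p = 0.648 with an estimated correlation), of which 3 were called and 2 of these also with the block. The related nspc family (15 genes) had a median of -0.33 (camera adjusted p = 0.0205; adjusted p = 0.648 with an estimated correlation; 0.133 without NL 3 and DL 2), with 0 called by limma and 5 at an unadjusted p under 0.05, and nspg (13 genes) a median of 0.06 (camera adjusted p = 0.819). Of 11 abu genes, 10 were negative with a median of -0.90 (camera adjusted p = 6.12e-06; adjusted p = 0.648 with an estimated correlation), and limma called 0, with 9 at an unadjusted p under 0.05. Under 4 other scalings the medians of the families ran from -1.29 to -1.23 (nspb), -1.34 to -1.25 (fipr) and -0.96 to -0.89 (abu). Similar copies make the split of reads among these genes uncertain.

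By the annotation, 12 protein-coding genes of the mitochondrial genome were tested, with a median log2 change of 0.26, and limma called 0, with 1 at an unadjusted p under 0.05. Their mean log2(FPKM + 1) was 9.70 ± 0.39 in NL and 10.02 ± 0.25 in DL (SD, n = 4 each; exact permutation p = 0.2, two-sided).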
